A study of Homo sapiens with 18 samples.

How the data were processed

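The labels describe 18 poly-A RNA libraries, 6 each of HepG2 and of the clones H33 and H12, grown in 1 medium and sequenced on an Illumina NovaSeq instrument; samples were grouped by the cell line and genotype labels. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.5.3a, RSEM without a version, edgeR 3.28.0 and the genome build GRCh38.p10, without giving the role or order of each. The files used here are 2 tables of the authors' own comparisons, H33 against HepG2 (14888 genes) and H12 against HepG2 (14896 genes). Per the file headers, each deposited row holds a log2 fold change of clone over HepG2 and a log2 CPM averaged over the libraries of that comparison. Per the file headers, each deposited row also holds a likelihood ratio, a score per gene from a generalized linear model. The deposited p-value equals the chi-square tail of that score with 1 degree of freedom, and the deposited adjusted p-value lies within 0.000152 (H33) and 0.000105 (H12) of the Benjamini-Hochberg adjustment over the listed genes. The p-value is listed as 0 for 1801 genes in H33 and 421 in H12. The filter on low counts, the scaling between libraries, the dispersion settings, the annotation release and the use of strand are not given in the sources used here.

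No values per library were used, so library depth is unknown, replicates could not be compared, and no group mean or SD was computed. Statistics were taken from the authors' deposited tables at an adjusted p of 0.05, in place of the count tests planned for files with counts. The standard error of a log2 fold change was derived as its absolute value divided by the root of the likelihood ratio. For genes with almost no reads in 1 group this value is not a sampling error and can be too small. Group levels were implied from the mean CPM and the fold change, assuming groups of equal size; HepG2 levels implied by the 2 tables differed with an SD of 0.00983 log2 units over 12744 genes above 1 CPM. Implied levels gathered at a floor under 0.00781 CPM, as for genes without reads in a group: 135 genes on the clone side in H33, 13 in H12, and 75 and 72 on the HepG2 side. Fold changes of such genes depend on the prior count. The medians of all fold changes were -0.02 in H33 and -0.03 in H12.

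Gene lists (40, with the genes around PRKACA and DNAJB1 among them) were fixed before the data were examined, from general knowledge of liver, fibrolamellar carcinoma, PKA and CDK7 biology. They were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the signed root of the likelihood ratio with a preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg adjusted over the 40 lists; an estimated correlation needs values per library. Symbols carried by 2 identifiers were left out of lists. The fold changes of H33 and H12 were compared by their difference over the root of their summed squared standard errors, Benjamini-Hochberg adjusted over 14765 shared genes. Shared controls make this test conservative, but standard errors that can be too small near the floor work the other way. The overlap was set beside 100 simulations of unchanged clones that share controls. Coordinates and biotypes come from GENCODE 29 on GRCh38, in which all identifiers of both tables were found. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used otherwise.

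The tests were tested on simulated data. For the H33 minus H12 difference over 14765 genes, with 200 genes changed in each of 20 simulations, 58.5% of changes of 0.5 log2 units, 79.7% of 1, 95.3% of 2 and 99.0% of 4 were recovered, and 0.509% of calls were false. For the H33 gene lists, on 14888 independent statistics, 94 of 100 lists shifted by 1 SD were called and 1 of 440 unshifted ones. The noise of the difference simulations was drawn from the implied standard errors, so errors in these would not show. Genes of real lists can move together, which the list simulations leave out. The simulated list statistics were normal, while the real ones range far wider, so very small p-values were not checked by them.

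Genes were named by a rule fixed at the same time as the lists. It takes PRKACA, DNAJB1, CDK7, CCNH, MNAT1 and the measured interval genes; per comparison the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a symbol and at least 2 log2 CPM; up to 4 called members of each described list with the largest absolute change; and, for both clones together, the 5 largest mean rises, the 5 largest mean falls and the 5 largest differences among genes called in opposite directions. Some genes that the rule takes are not named or plotted singly, and no others took their place; counts, medians and tests include them. Genes named outside it are marked as chosen after their values were seen. Genes with near-identical copies, such as AKR1C, UGT1A, UGT2B, ORM and HLA genes, and genes that overlap others are uncertain, since the authors' counting could split their reads. Alternatives were a threshold of 0.01, a minimum absolute log2 fold change of 1, Bonferroni adjustment, a minimum of 1 log2 CPM, centring on the median of all genes, other correlations and other statistics for the lists. Genes on the sex chromosomes were left out of scans along chromosomes.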

Results

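Poly-A RNA was sequenced from 18 libraries of human liver cancer cells in 3 groups of 6. HepG2, a hepatoblastoma line without an engineered fusion, was the control. H33 and H12 are described by the labels as HepG2 clones with the DNAJB1-PRKACA fusion, the event that defines fibrolamellar carcinoma: it joins the first part of DNAJB1, a heat shock co-chaperone, to PRKACA, the catalytic subunit of the cAMP-dependent protein kinase PKA. The study set each clone beside HepG2 to find the genes that differ in fusion-bearing cells, under a title that names the transcription-linked kinase CDK7. The values used here are 1 table of test statistics per clone, so the depth of each library and the spread between libraries are unknown. They hold no genotypes, so the descent of the clones from this HepG2 stock was not checked, and a fold change covers every difference between the lines, not the fusion alone. Fold changes are log2 ratios of clone over HepG2, and the standard error (SE) beside a fold change is the one implied by that change and its likelihood ratio. The labels call the 6 samples of a group biological replicates without saying that they came from separate cultures, so p-values measure the spread between these samples only.

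PRKACA rose in both clones, and DNAJB1 moved little. In the authors' deposited tables PRKACA (ENSG00000072062, GRCh38 chromosome 19 from 14091688 to 14118084) had a log2 fold change of 2.15 (SE 0.03) in H33 and 2.07 (SE 0.14) in H12. This corresponds to 444% and 421% of the HepG2 level, with an adjusted p listed as 0 in H33 and 2.02e-48 in H12. DNAJB1 (ENSG00000132002, chromosome 19 from 14514770 to 14529770) stood at -0.20 (SE 0.04) in the authors' deposited table for H33, past the threshold, and at -0.25 (SE 0.13, adjusted p = 0.0609) in that for H12, which is not past it. Values per gene do not separate reads of the fusion from those of the intact genes. CDK7 was higher by 0.24 in both of the authors' deposited tables (SE 0.05 in H33 and 0.06 in H12). Of its partners in the CDK-activating kinase, the assembly factor MNAT1 rose by 0.55 (SE 0.06) in H33 and 0.53 (SE 0.05) in H12, while cyclin H (CCNH) stood at -0.04 and -0.09, past the threshold in neither of the authors' deposited tables.

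In tumours the fusion arises from a deletion that takes in the segment between PRKACA and DNAJB1. The genes lying there, over 396685 bases between the annotated gene ends, were therefore set beside their neighbours. In the authors' deposited tables, the adhesion receptor genes ADGRL1 and ADGRE5 rose by 4.34 (SE 0.10) and 3.01 (SE 0.07) in H33, and by 4.16 (SE 0.11) and 2.82 (SE 0.09) in H12. The helicase gene DDX39A (0.72 and 0.65) and the histone chaperone gene ASF1B (0.39 and 0.36) were higher in both of the authors' deposited tables, and the scaffold gene GIPC1 was higher in H33 (0.40) and not past the threshold in H12 (0.14). The median of the 6 measured interval genes was 0.56 in H33 against 0.00 for 18 flanking genes (two-sided exact permutation test, p = 0.401), and 0.50 against -0.17 in H12 (exact permutation p = 0.330). A difference between interval and flank was therefore not shown in either clone. With 6 interval genes, and flank values from -3.98 to 6.91 in H33, this test cannot exclude the loss of a copy. The list test sets each list against all other genes and so does not compare interval with flank. Neither the interval (adjusted p = 0.165 in H33 and 0.161 in H12) nor the flank (0.538 and 0.845) passed it. After adjustment over the list alone, 5 interval genes were higher and 1 lower in H33, and 4 and 1 in H12; the flank had 8 and 8, and 8 and 9.

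**Figure D1:**
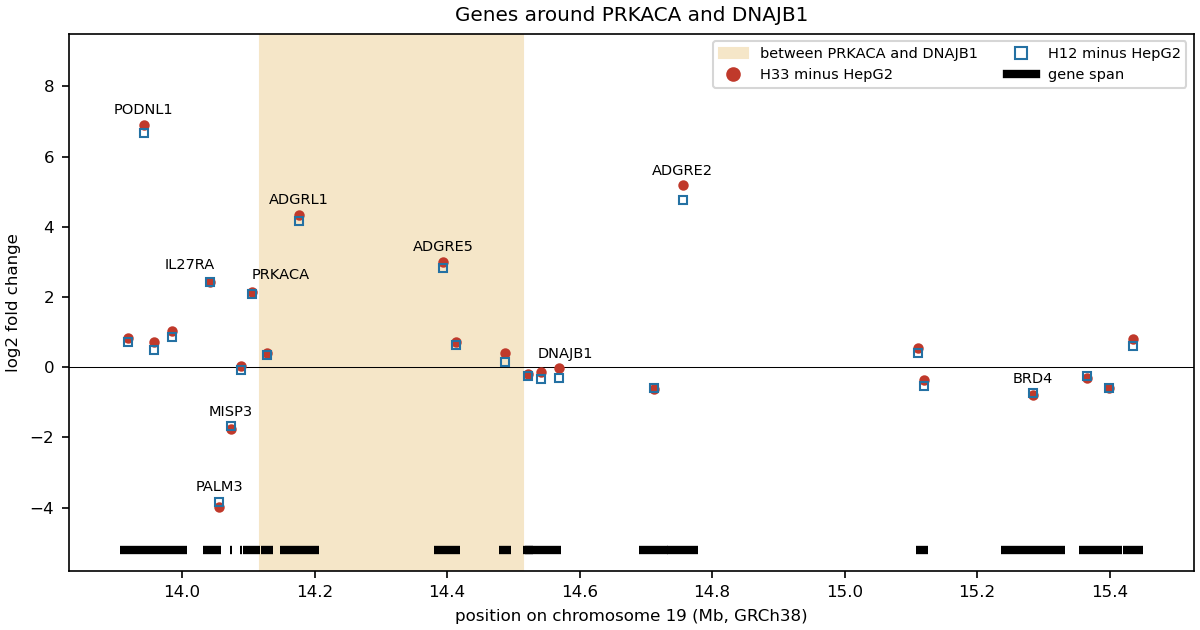
Log2 fold change of H33 (filled circles) and H12 (open squares) over HepG2, from the authors' deposited tables, against position on chromosome 19 in Mb, for the 18 flanking genes, 5 of the 6 interval genes, PRKACA and DNAJB1; black bars are gene spans and the shaded part lies between the 2 fusion partners. Inside it ADGRL1 (4.34 in H33) and ADGRE5 (3.01) lie highest, while genes outside range from PALM3 (-3.98) to PODNL1 (6.91).

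H33 cells had lower levels of hepatocyte genes and higher levels of most measured neuroendocrine, matrix, interferon-stimulated and mitotic genes than HepG2. All 33 measured genes for secreted hepatocyte proteins were lower in the authors' deposited table for H33, with a median log2 fold change of -8.98, or -8.62 with levels under 0.1 CPM set to 0.1 CPM. The fetal plasma protein gene AFP fell from an implied 4111 CPM (counts scaled to a common library total) in HepG2 to 0.0372 CPM, a change of -16.75 (SE 0.12). With so low a level in 1 group, here and below, the SE is not a sampling error and can be too small. The hepatocyte nuclear factor gene HNF4A stood at -8.79 (SE 0.06) in the authors' deposited table. At the other end, the granin gene SCG2, a component of secretory granules, rose by 14.04 (SE 0.11) to an implied 2392 CPM. In total 13334 of the 14888 genes in the authors' deposited table were past an adjusted p of 0.05, 6587 higher and 6747 lower. With an absolute log2 fold change of at least 1 there were 6626, and 859 rose and 1110 fell by at least 32-fold.

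Rises and falls were ranked among called genes with a symbol and at least 2 log2 CPM. The largest rises in the authors' deposited table for H33, after SCG2, included the adhesion molecule VCAM1 (11.45, SE 0.16), the pyruvate dehydrogenase kinase PDK4 (10.31, SE 0.16), GRAMD1B (10.15, SE 0.10) and the kallikrein-related protease KLK7 (10.12, SE 0.17). SNAP25, LMNTD1, TNFRSF6B, KLK8 and KLK10 reached implied levels of 51.9, 16.1, 18.2, 14.8 and 9.92 CPM, while HepG2 lay at the fitted floor of the authors' deposited table, about 0.005 CPM. A fitted fold change against that floor depends on the prior count and is no bound, so none is given. The largest falls after AFP with a level above the floor were those of DLK1 (-12.66, SE 0.11), a fetal liver antigen, the antithrombin gene SERPINC1 (-12.50, SE 0.11) and the amino acid transporter gene SLC38A3 (-12.48, SE 0.12) in the authors' deposited table. UGT2B4, DZIP1, AGXT, MPDZ and HNF4G fell from implied HepG2 levels of 51.0, 40.8, 34.0, 33.5 and 28.8 CPM to the floor. The tables hold no counts, so no lower limit of these falls can be set.

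Among the liver lists, the authors' deposited table for H33 had all 23 hepatocyte transcription factors lower (median -6.25), among them FOXA3 (-8.97) and the bile acid receptor gene NR1H4 (-8.78). Of 24 genes of bile acid and xenobiotic metabolism 23 fell, with a median of -6.13; examples are the bile acid 12-alpha-hydroxylase CYP8B1 (-9.14) and the sulfotransferase SULT2A1 (-9.20). CYP1B1 was the exception on that list, named here after its value was seen (5.89). Of the urea cycle and ammonia list 17 of 19 fell (median -1.52), including the arginase ARG1 (-10.08) and OTC (-5.95). Wnt and beta-catenin targets had 16 of 19 lower, 1 higher and 2 not past the threshold; the ammonia transporter gene RHBG (-8.89) and the transcription factor SP5 (-8.71) were among them in the authors' deposited table. Of 18 biliary and progenitor markers 15 were lower, such as LIN28B (-11.98) and GPC3 (-9.45), while the mucin MUC1 (8.43) and the keratin KRT19 (2.36) were higher. Camera on the signed statistic set these lists apart from the other genes as lower, with adjusted p of 3.72e-84 (secreted proteins), 1.38e-12 (transcription factors), 5.52e-14 (bile acid and xenobiotic), 0.000270 (urea cycle), 7.18e-16 (Wnt) and 5.62e-18 (biliary and progenitor). With ranks in place of the statistic, camera gave these lists adjusted p between 5.00e-15 (secreted proteins) and 0.000134 (urea cycle). Those of Wnt targets and of biliary and progenitor markers were 9.24e-06 and 5.68e-05 by camera with ranks. The counts adjusted over the list alone were the same in H33 for all 40 lists.

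Lipid, hypoxia and stress lists were lower as well. Cholesterol synthesis had 20 of 24 genes lower in the authors' deposited table for H33 (median -1.30), including STARD4 (-9.53) and MSMO1 (-3.69), with INSIG1, which restrains the pathway's activation, higher by 5.61. Fatty acid synthesis and storage had 19 of 24 lower (median -2.32), among them the lipid droplet gene CIDEB (-10.01) and its relative CIDEC (-6.63), while the malic enzyme ME1 rose by 7.90. For hypoxia response genes 18 of 21 were lower (median -2.15), with the collagen crosslinker LOX at -10.31 and the mitophagy receptor BNIP3 at -8.74. The unfolded protein and integrated stress response had 22 of 25 lower in the authors' deposited table (median -1.26), such as SLC7A11 (-3.30) and TRIB3 (-2.32), with CHAC1 higher (6.13). Their adjusted p by camera were 2.48e-06, 0.000146, 0.000114 and 0.00152, in that order. With the log2 fold change as the statistic the stress response call ended (adjusted p = 0.529).

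Lists that passed as higher in H33 were G2 and M phase, matrix, neuroendocrine and interferon-stimulated genes. Of 30 genes of G2 and M phase 27 were higher and 1 lower in the authors' deposited table (median 1.15), among them UBE2C (1.97, SE 0.04), CDC20 (1.80, SE 0.05), HMMR (1.70, SE 0.04) and ANLN (1.65, SE 0.04). The S phase list was mixed, with 16 higher and 13 lower, such as CCNE2 (1.68) and POLA1 (1.13) against MCM3 (-1.35) and CDC25A (-1.18). Extracellular matrix genes had 17 of 24 higher and 6 lower (median 3.98), led by the collagens COL1A2 (8.54), COL4A1 (7.37) and COL6A2 (7.02), with the protease inhibitor TIMP3 lower (-9.52). Of 8 measured neuroendocrine genes 7 rose in the authors' deposited table: next to SCG2 these included the neuropeptide genes NTS (9.98), GAL (7.32) and VGF (6.40). The neuroendocrine list holds 22 genes, and the others were not measured. A gene silent in HepG2 may be measured only where it rose in the clone. The neuroendocrine count and list test can thus be tilted upward. Interferon-stimulated genes had 19 of 25 higher and 5 lower (median 1.01), led by IFITM1 (7.92), IFIT2 (5.52) and OAS2 (4.97). Camera gave adjusted p of 1.23e-05 (G2 and M phase), 0.0238 (matrix), 0.0210 (neuroendocrine), 0.000114 (interferon) and 0.699 (S phase). With a preset correlation of 0.05 the matrix call was lost (adjusted p = 0.123), and with the log2 fold change as the statistic that of G2 and M phase (adjusted p = 0.151).

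Genes of the PKA pathway moved strongly in both directions. Of 40 PKA subunits and regulators, 18 were higher and 19 lower in the authors' deposited table for H33: the regulatory subunit gene PRKAR2B rose by 8.48 (SE 0.13), the phosphodiesterases PDE4B and PDE10A by 9.13 (SE 0.33) and 7.44 (SE 0.09), and the adenylyl cyclase ADCY3 by 6.90 (SE 0.11). The adenylyl cyclase ADCY1 fell from an implied 3.21 CPM to the floor. Of 24 cAMP and CREB targets 15 were higher and 8 lower, with the potassium channel KCNK3 at 7.66, against the gluconeogenic genes G6PC1 (-11.63) and PPARGC1A (-9.77). Fibrolamellar carcinoma markers had 12 of 21 higher and 7 lower in the authors' deposited table, led by NTS, DNER (8.35), SLC16A14 (7.99) and, among the falls, COL9A3 (-8.10). The 24 genes of the CDK7 complex and of transcriptional kinases lay between -0.81 and 1.09 in the authors' deposited table, 13 higher and 7 lower, with CDK9 at 1.09 (SE 0.06), ERCC2 at 0.96 and MED12 at 0.95. None of these lists passed as a set in H33 (adjusted p = 0.374 for PKA, 0.610 for CREB targets, 0.0503 for fibrolamellar markers and 0.476 for the CDK7 list). Among genes with at least 1 log2 CPM the fibrolamellar markers passed as higher (adjusted p = 0.0219). By camera they did not pass with ranks (adjusted p = 0.238), the log2 fold change as the statistic (0.421) or a preset correlation of 0.05 (0.175).

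The remaining lists did not pass in H33 either, although most of their genes did. In the authors' deposited table all 13 mitochondrially encoded transcripts were lower (median -0.61), with MT-ND3 at -1.75 and MT-CO1 at -1.03 (list adjusted p = 0.538), while the 39 nuclear respiratory chain subunits split into 16 higher and 20 lower (0.892). Higher and lower members numbered 6 and 14 of 21 for fatty acid oxidation (0.925), 13 and 12 of 27 for glycolysis and gluconeogenesis (0.925), 8 and 8 of 17 for cyclins and CDK inhibitors (0.925), 8 and 12 of 20 for p53 targets (0.436), and 15 and 6 of 21 for apoptosis regulators (0.517). For epithelial-mesenchymal transition they numbered 8 and 10 of 19 (0.925), with CD44 (8.04) and VIM (6.77) higher, EPCAM (-7.30) lower and CDH2 falling from an implied 10.2 CPM to the floor in the authors' deposited table. This list mixes epithelial with mesenchymal genes, which would move in opposite directions. Its counts and tests therefore cannot decide on a transition in either clone. Higher and lower members numbered 14 and 6 of 22 for heat shock proteins (0.101), with HSPB1 at 3.19, 8 and 13 of 21 for NRF2 targets (0.109), and 13 and 4 of 18 for NF-kB and inflammatory genes (0.159), with TNFAIP2 (7.54) and CXCL5 (7.40) higher and ICAM1 (-8.03) lower. They numbered 10 and 14 of 26 for growth factor receptors (0.374), 9 and 8 of 18 for YAP and TEAD targets (0.925), and 9 and 14 of 28 for ribosomal proteins (0.925). Housekeeping reference genes had 11 and 3 of 16 (0.0785), with HPRT1 at 1.96, ACTB at 1.60 and GAPDH at 1.05 in the authors' deposited table. Markers of other cell types were few: fibroblast genes had 3 higher and 3 lower (0.538), endothelial genes 0 and 3 (0.698), leukocyte genes 1 and 4 (0.0503) and cholangiocyte genes 4 and 1 (0.925). With ranks, NF-kB (adjusted p = 0.0471) and housekeeping genes (0.0221) passed as higher in H33. Leukocyte genes passed as lower with the log2 fold change as the statistic (0.0371) and with at least 1 log2 CPM (0.0130).

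**Figure D2:**
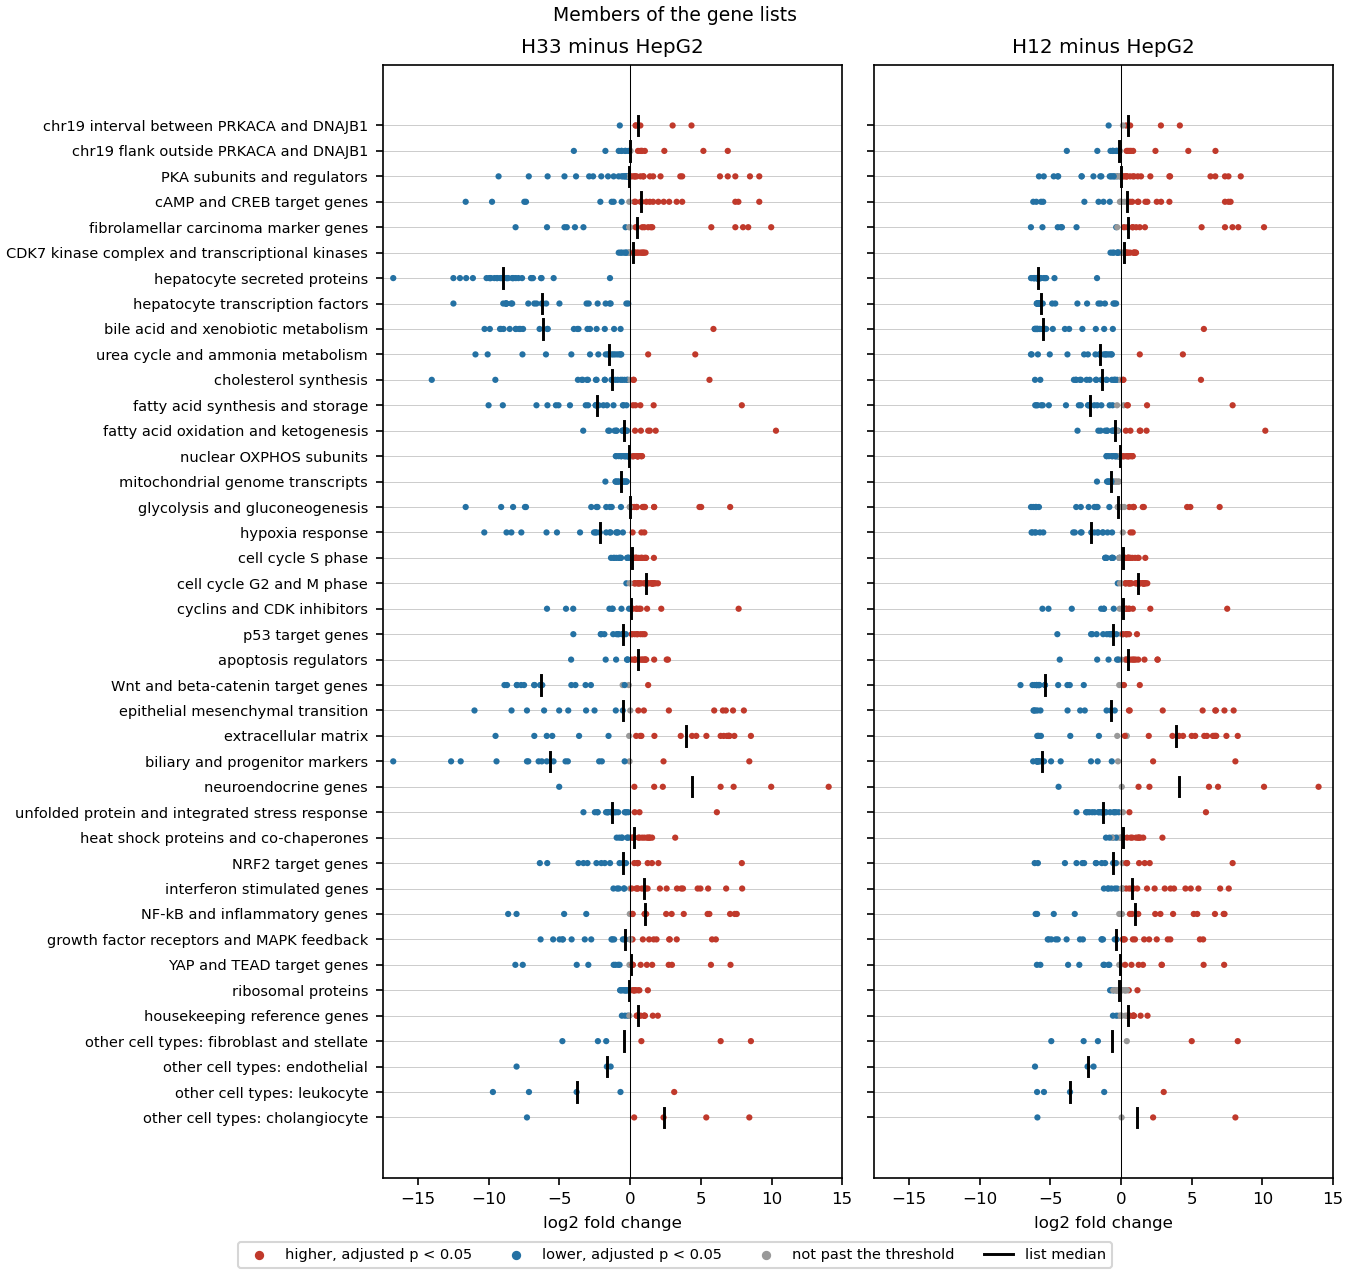
Log2 fold change of each measured member of the 40 gene lists for H33 (left) and H12 (right) over HepG2, from the authors' deposited tables; colour gives the call at an adjusted p of 0.05 and the black bar is the list median. Secreted hepatocyte proteins have a median of -8.98 in H33 and -5.87 in H12, and G2 and M phase genes 1.15 and 1.17.

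H12 cells also had lower levels of hepatocyte genes and higher levels of most measured neuroendocrine, matrix, interferon-stimulated and mitotic genes than HepG2. All 33 secreted hepatocyte proteins and all 23 hepatocyte transcription factors were lower in the authors' deposited table for H12 (medians -5.87 and -5.67), SCG2 rose by 13.97 (SE 0.60), and 26 of 30 G2 and M phase genes were higher. In total 12817 of 14896 genes in the authors' deposited table were past the threshold, 6224 higher and 6593 lower, and 6564 of them with an absolute log2 fold change of at least 1. Genes nearly absent from H33 gathered near 1 value in H12. The 160 genes that were under -9 in H33, with an implied HepG2 level of at least 10 CPM, had a median of -5.93 in the authors' deposited table for H12 (SD 0.203), which is 1.64% of the HepG2 level, against -9.87 (SD 1.17) in H33. Many liver genes in H12 lay near that value, with an implied SE of 1.47 for AFP (-5.94) and 1.54 for AHSG (-6.14) in the authors' deposited table.

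As in H33, rises and falls were ranked among called genes with a symbol and at least 2 log2 CPM. Less abundant genes could fall further, as DKK4 did (-7.11). The 10 largest rises in the authors' deposited table for H12 held, besides SCG2, VCAM1 (11.06, SE 0.18), PDK4 (10.20, SE 0.16), GRAMD1B (10.18, SE 0.21) and NTS (10.11, SE 0.17). SNAP25, TNFRSF6B, LMNTD1, the class II histocompatibility gene HLA-DRA and the homeobox gene LHX1 reached implied levels of 24.9, 15.4, 14.7, 11.9 and 8.47 CPM, with HepG2 at the floor. HLA genes share sequence, so HLA-DRA is uncertain. The 10 largest falls lay between -6.93 and -6.43 in the authors' deposited table: ANGPTL8, CLDN19, CSF3R, AGXT, CCR6, UPK3A, HPN, CYP2W1, CRYAA and VWA1. Of these, AGXT was also among the 10 largest falls in H33. ANGPTL8 stood at -6.93 (SE 0.33) and CLDN19 at -6.65 (SE 0.18).

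By list, the authors' deposited table for H12 had 23 of 24 bile acid and xenobiotic genes lower, with CYP27A1 at -6.07 (adjusted p = 0.0163), and 17 of 19 urea cycle genes, with ARG1 at -5.88 and OTC at -5.04 (0.00594). Cholesterol synthesis had 20 of 24 lower (0.0191), with MSMO1 at -3.33 and INSIG1 at 5.65. Fatty acid synthesis and storage had 18 of 24 lower (0.0338), hypoxia response 18 of 21 (0.00454) with CA9 at -6.28, Wnt targets 15 of 19 (0.0250) and the stress responses 22 of 25 (0.0163) with XBP1 at -2.40 in the authors' deposited table. The secreted proteins passed as a list at 0.0354 and the transcription factors at 0.00464. Lists that passed as higher were G2 and M phase (0.0191), with UBE2C at 1.86 (SE 0.09), matrix (16 of 24 higher and 6 lower, 0.00173), neuroendocrine (6 of 8 higher and 1 lower, 0.00480), interferon (16 of 25 higher and 6 lower, 0.00173), NF-kB and inflammatory genes (11 of 18 higher and 4 lower, 0.000237) and fibrolamellar markers (12 of 21 higher and 7 lower, 0.0133). For neuroendocrine genes the limit of 8 measured members given for H33 applies here too. With a preset correlation of 0.05, 4 of the 15 lists passed in H12: matrix, neuroendocrine, interferon and NF-kB. The others reached adjusted p of 0.0527 (hypoxia) to 0.207 (secreted proteins). With the log2 fold change as the statistic, adjusted p was 0.124 for G2 and M phase, 0.292 for the stress responses, 0.120 for NF-kB genes and 0.347 for fibrolamellar markers, and cholesterol synthesis was no longer past the threshold either. With ranks the fibrolamellar markers reached 0.347, and with at least 1 log2 CPM fatty acid synthesis reached 0.0507 and secreted proteins 0.0696. Whether a list differed between H33 and H12 was not tested.

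Of the lists that did not pass in H12, PKA subunits and regulators had 18 higher and 16 lower in the authors' deposited table (0.157), with PRKAR2B at 8.47 (SE 0.14) and PDE4B at 7.60 (SE 0.37). CREB targets had 12 and 8 (0.0933), the CDK7 list 13 and 7 (0.682) with MED12 at 1.06, GTF2H3 at 0.94 and GTF2H1 at 0.91, and biliary and progenitor markers 2 and 15 (0.432). With the log2 fold change as the statistic the biliary and progenitor markers passed as lower in H12 (adjusted p = 4.14e-06). Mitochondrially encoded transcripts had 8 of 13 lower (0.518), 7 after adjustment over the list alone. Ribosomal proteins had 2 higher and 4 lower of 28 (0.843), 1 and 1 over the list alone, and housekeeping genes 9 and 2 of 16 (0.843), 8 and 2 over the list alone; in the other 37 lists the 2 counts were the same. The rest were S phase (14 and 9, 0.981), nuclear respiratory chain (15 and 16, 0.845), fatty acid oxidation (6 and 13, 0.967), glycolysis (9 and 12, 0.967), cyclins (8 and 7, 0.967), p53 targets (6 and 12, 0.140), apoptosis (13 and 5, 0.589), epithelial-mesenchymal transition (8 and 11, 0.589), heat shock (10 and 4, 0.737), NRF2 targets (6 and 12, 0.445), growth factor receptors (12 and 14, 0.966), YAP and TEAD targets (8 and 8, 0.477), and fibroblast (2 and 3, 0.721), endothelial (0 and 3, 0.230), leukocyte (1 and 4, 0.493) and cholangiocyte markers (2 and 1, 0.230), with counts of higher and lower members in the authors' deposited table and the adjusted p.

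Precision differed between the 2 tables for abundant genes. Among 259 genes at 8 log2 CPM or more with an absolute H33 log2 fold change of 0.3 to 1, the median implied SE was 0.0346 in H33 and 0.194 in H12, and 259 and 189 of them were called in the authors' deposited tables. Below 4 log2 CPM the SE were alike, with a ratio of 0.963 over 1610 genes. Counts of called housekeeping, ribosomal and mitochondrial genes in H33 and H12 were thus made at different precision. Median, mean and test direction differed in sign for some lists that did not pass: PKA, nuclear respiratory chain, ribosomal proteins (H33), the chromosome 19 flank, glycolysis, growth factor receptors (H12), and fatty acid oxidation, cyclins, epithelial-mesenchymal transition, YAP targets and fibroblast markers (both).

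**Figure D3:**
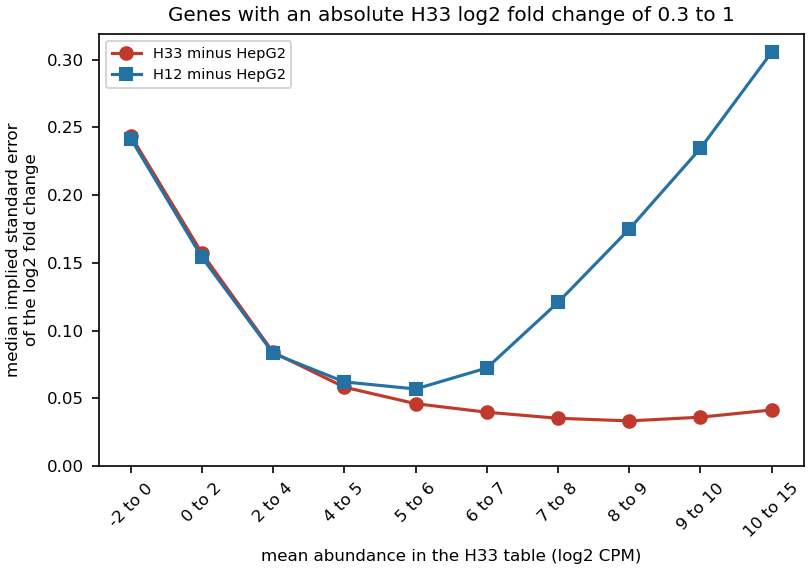
Median implied standard error of the log2 fold change, for H33 (circles) and H12 (squares) over HepG2, against mean abundance in log2 CPM, for genes with an absolute H33 log2 fold change of 0.3 to 1. Both fall to 0.046 (H33) and 0.057 (H12) at 5 to 6 log2 CPM, and that of H12 then climbs to 0.306 above 10 log2 CPM, where H33 has 0.041.

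Fold changes of the clones followed each other closely. Of 14765 genes in both of the authors' deposited tables, 5971 were higher and 6325 lower in both, against 2691 and 2998 for independent lists. Across genes, which are not independent replicates, the fold changes had Pearson's r of 0.979 and Spearman's rho of 0.993. Both comparisons use the same HepG2 libraries: simulated unchanged clones against shared controls gave a mean r of 0.280, rho of 0.332 and 0 genes called the same way. The covariance was 7.80, beside 0.00971 in the simulation. Since no gene was changed in the simulation, its 0 shared calls followed from the setting. It covers only the random error of shared controls, and not real traits of the HepG2 libraries that both fold changes carry. The shared controls could not be split without values per library. The largest mean rises were those of SCG2, SNAP25, TNFRSF6B, LMNTD1 and VCAM1, and the largest mean falls included those of AFP, UGT2B4, DZIP1 and AGXT. Opposite calls in the authors' deposited tables were made for 5 genes: TTYH1 (0.98 in H33 and -0.44 in H12), ANKEF1 (0.18 and -0.50), TCF7 (-0.39 and 0.21), MRPL52 (0.18 and -0.20) and P3H1 (0.17 and -0.14).

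**Figure D4:**
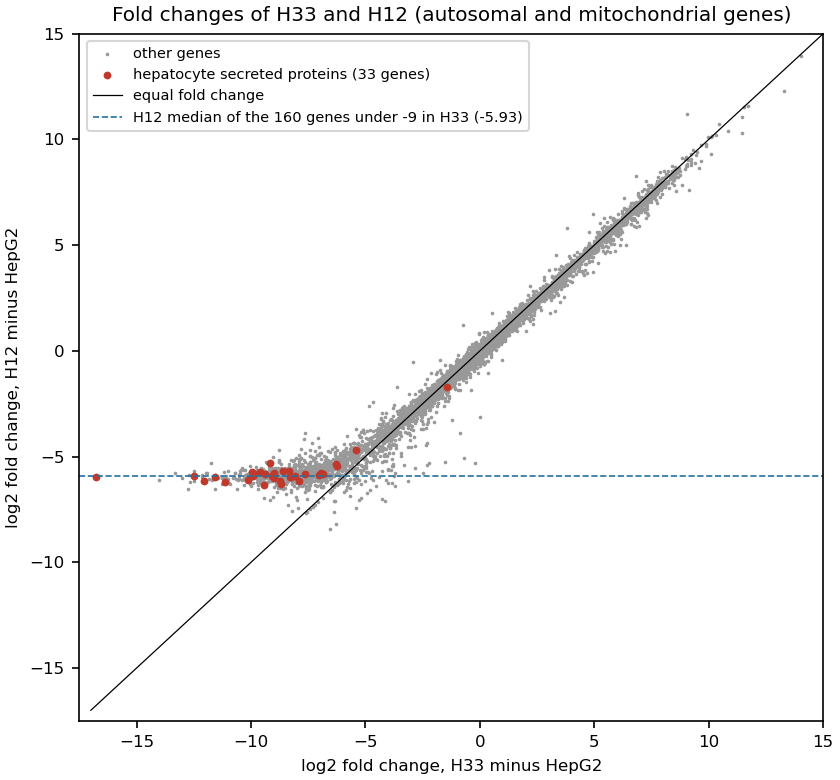
Log2 fold change of H12 over HepG2 against that of H33 over HepG2, from the authors' deposited tables, 1 point per gene outside the sex chromosomes; red points are the 33 secreted hepatocyte proteins, the solid line marks equal change and the dashed line the median of -5.93 in H12 of genes under -9 in H33. Points follow the line of equal change down to about -5, below which many H12 values lie near the dashed line, as for AFP (-16.75 and -5.94).

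Tested directly, 797 of the 14765 shared genes differed between the clones, with a lower value in H33 for 574 and a higher one for 223. Of these, 482 had an H33 log2 fold change under -5 in the authors' deposited table and were lower in H33. The implied SE can be too small for genes near the floor, so 797 is not a lower bound. The number of genes that differ between the clones was 1363 with a correlation of 0.5 between the fold changes, and 202 among genes above -4 in H33. For the 8244 genes within 1 log2 unit of HepG2 in H33, the H33 minus H12 difference had a median of 0.00 and an SD of 0.167.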

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

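All tests of explanations in this part were chosen after the results were seen, except that of genes at equal level in HepG2 and H33, whose bounds were set beforehand. The fold changes of H33 and H12 differed by the direct test for 797 genes. By the same test the 5 genes called in opposite directions differed, with H33 minus H12 log2 differences of 1.42 (TTYH1), 0.68 (ANKEF1), -0.59 (TCF7), 0.38 (MRPL52) and 0.31 (P3H1). These 5 were selected on the same fold changes that the test uses, so its outcome is no separate evidence for them. Among genes above -4 in H33 and at 2 log2 CPM or more in at least 1 of the tables, chosen after their values were seen, the largest differences were -2.39 (NR5A2, a liver nuclear receptor), -2.16 (HLA-DRA), -1.99 (STC1), -1.94 (GRB10) and -1.45 (HLA-DRB1), and on the side higher in H33 2.71 (UGT1A1), 2.25 (PGC), 1.65 (TUBA4A), 1.38 (ELF5) and 1.30 (CYP1A1). HLA-DRA lay at the floor in HepG2, so the size of its difference depends on the prior count; its implied levels were 2.99 CPM in H33 and 11.9 CPM in H12. HLA and UGT1A genes share sequence and are uncertain, and UGT1A1 (-5.54) and PGC (-6.25) have H12 fold changes within the range of the genes nearly absent from H33 (-6.54 to -5.32). Of other named genes, PDE4B (1.54), CA9 (1.10) and KLK7 (0.80) were higher in H33 by the same test.

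Other named genes were lower in H33 by this test, with H12 log2 fold changes between -6.65 (CLDN19) and -5.51 (PPARGC1A) in the authors' deposited table. Their H33 minus H12 differences were -10.81 (AFP), -7.52 (UGT2B4), -6.97 (DZIP1), -6.85 (MPDZ), -6.80 (HNF4G), -6.57 (SERPINC1), -6.45 (DLK1), -6.33 (SLC38A3), -6.20 (AGXT), -6.19 (LIN28B), -5.90 (AHSG), -5.64 (G6PC1), -5.61 (APOA2), -5.31 (CDH2), -5.07 (CCR6), -4.92 (APOB), -4.28 (LOX), -4.26 (PPARGC1A), -4.19 (ARG1), -4.06 (CSF3R), -3.94 (CIDEB), -3.82 (STARD4), -3.50 (ADCY1), -3.17 (CYP8B1), -3.11 (FOXA3), -2.87 (NR1H4), -2.74 (SP5), -2.32 (UPK3A), -2.27 (CYP2W1) and -1.59 (CLDN19). For 4 of the 6 genes of a block on chromosome 9 they were -3.04 (FOCAD), -3.02 (MTAP), -2.62 (KLHL9) and -1.84 (MLLT3), while the other genes of the block, CDKN2A (-0.32, adjusted p = 0.990) and CDKN2B (0.60, adjusted p = 0.744), did not pass this test. Several of these genes lie at the H33 floor, where the size of the difference and its implied SE depend on the prior count.

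The gathering of H12 fold changes near -5.93 was weighed over the 160 genes under -9 in H33. A shift in the scaling of the H12 table is argued against, since genes within 1 log2 unit of HepG2 in H33 had a median H12 minus H33 difference of -0.00048. Residual transcription set gene by gene in H12 is argued against for these genes by the absence of a low tail: 0 of the 160 genes lay more than 1 log2 unit below their H12 median, against 36 in H33. Genes outside this set were not weighed, though CLDN19 stood at -6.65 (SE 0.18) in H12 and the lowest value of any gene was -8.42. HepG2 RNA in the H12 libraries is a candidate explanation, since it would give all the 160 genes 1 share, and their SD was 0.203 in H12 against 1.17 in H33. Unequal shares between the 6 H12 libraries may add to it: at 4 to 8 log2 CPM the median implied SE of the genes under -9 in H33 was 7.26 times that of genes rising by at least 32-fold, against 1.12 times in H33. Whether such RNA came from unconverted cells in the clone, from handling or from the sequencing run, and in which libraries, is open without values per library.

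The climb of H12 standard errors with abundance was the second pattern. Mixing of HepG2 RNA cannot by itself move genes at equal level in both cells, yet 67 such genes at 8 log2 CPM or more had an H12 SE 5.75 times that in H33, so direct mixing is argued against as the whole source. A spread estimate that the authors' model shares between genes of like abundance, raised by the uneven liver genes, could give the ratio of 5.62 found for genes with a change of 0.3 to 1. It cannot be told apart from a true spread of abundant genes between H12 libraries, because the dispersion settings and the values per library are not at hand. No biological explanation was tested for this second pattern.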

How the results depend on the processing

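No paired analysis was possible because the tables hold statistics of whole groups and no values per library, although the labels number the samples 1 to 6 in each group. For the same reason DESeq2, other size factors, a replicate block, a fit of all 3 groups, no filter on low counts, another pseudocount, leaving out replicates, splitting the controls, estimated list correlations and other splits of the samples were not run, and what depth limits is unknown. The restrictions to genes above -4 in H33 and to genes of at most 6 log2 CPM, and the level minimum of 0.1 CPM, were chosen after seeing the data. With an absolute log2 fold change of at least 1, which calls fewer genes by construction, genes changed in H33 against HepG2 numbered 6626, genes changed in H12 against HepG2 6564 and genes changed in both clones 6236. With an adjusted p under 0.01, Bonferroni adjustment or at least 1 log2 CPM they numbered 11276 to 12871 in H33 and 10375 to 12177 in H12, and with at most 6 log2 CPM 10076 and 10026. The count of genes that differ between the clones was 1363 with a correlation of 0.5 between the fold changes, which narrows the standard error by construction, 202 above -4 in H33, where fewer genes are tested, 563 at an adjusted p under 0.01 and 613 with at least 1 log2 CPM. Over the alternatives 13 to 16 lists passed in H33 and 11 to 14 in H12, except 4 in H12 with a preset correlation of 0.05; the cause was not tested. The median of the chromosome 19 interval genes, and their mean (1.36 in H33 and 1.21 in H12), stayed positive. Centring on the median of all genes changed no direction among named genes, and no list median changed sign with levels under 0.1 CPM set to 0.1 CPM. Of the calls of named genes 4 ended at an adjusted p under 0.01, 32 with Bonferroni adjustment and 52 with a minimum change of 1.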

Other observations

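Whole gene clusters were switched together. All 9 measured HOXB genes from HOXB2 to HOXB13 on chromosome 17 (48540894 to 48729178), which pattern the body axis, rose by 6.80 to 9.66 in the authors' deposited table for H33 and by 6.77 to 9.73 in that for H12. A second run of 6 neighbours on chromosome 1, with S100A11, TCHH, S100A9, S100A6, S100A5 and S100A4, mostly calcium-binding proteins, rose by 5.21 to 7.88 and 4.72 to 7.82. Silenced runs were sought among 11212 autosomal coding genes with an implied HepG2 level of at least 1 CPM. Measured genes below that level were skipped and could lie between members. Runs of 6 or more such neighbours that fell under 10% of the HepG2 level in H33 numbered 4. Of these, 3 held genes of the liver lists: the SERPINA genes on chromosome 14, UGT2B and UGT2A genes with SULT1E1 and ODAM on chromosome 4, and CHST9, CDH2, DSC3, DSC2, DSG2 and TTR on chromosome 18. These runs and their genes were chosen after their values were seen, as were all tests in this part.

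The fourth run held MLLT3, FOCAD, KLHL9, MTAP, CDKN2A and CDKN2B on chromosome 9 (20341665 to 22009363), the last 2 being inhibitors of cell cycle kinases. In the authors' deposited table for H33 they stood between -8.72 and -4.54, with FOCAD, KLHL9 and MTAP at 0.237%, 0.285% and 0.240% of the HepG2 level, and in that for H12 between -6.19 and -5.13. The nearest measured genes on either side, AL158206.1 and ACER2 before the block and CAAP1 and PLAA after it, stood in H33 at 55.3%, 56.4%, 64.3% and 133.4% of the HepG2 level. Of the other neighbours examined, PLIN2 and C9orf72 were lowest (27.0% and 23.3%) and IFT74 highest (176.4%). Of 1000 shuffles of gene order within chromosomes, over the same 11212 genes, 9 held a run of this length anywhere on the autosomes (permutation p = 0.01). Any of the 4 runs found would give this p, and the run length was set after the data were seen. Chance placement of this block itself was therefore not decided. Loss of the segment in both clones is a hypothesis that cannot be told apart from shared silencing here, since 0 measured genes other than these 6 lie between the retained neighbours, which are up to 7.39 Mb apart. Silencing of liver genes stays open as well: 0 of the 6 are on the 4 liver lists, but the lists are short. A loss would be settled by DNA from HepG2 and both clones.

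Whole chromosomes were shifted as well. Over 8011 coding genes with an implied level of at least 8 CPM in HepG2 and H33, the median H33 log2 fold change was -0.65 on chromosome 20 and 0.57 on chromosome 21, and -0.62 and 0.58 in H12. The SD of the 22 autosome medians was 0.291 in H33, against at most 0.0958 in 1000 shuffles of genes over chromosomes (permutation p = 0.001, the smallest they can give). Chance spread over the chromosomes is thereby argued against, with the limit that neighbouring genes are not independent. Different chromosome copy numbers in the clones and in the HepG2 libraries are a candidate explanation, which was not tested because the tables hold no DNA measurement. Another is that H33 and H12 may not derive from the HepG2 stock sequenced here, which could also bear on the HOXB genes, the chromosome 9 block and the share of genes called (89.6% in H33 and 86.0% in H12). It was not tested either; genotypes of the 3 lines would show it.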
